A study of Mus musculus with 4 samples.

How the data were processed

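Contacts bound by cohesin were measured in mouse erythroleukemia (MEL) cells by chromatin interaction analysis with paired-end tag sequencing (ChIA-PET) after precipitation with an antibody to SMC1, a core subunit of the cohesin ring. Per the labels, 2 biological replicates were made of uninduced cells and 2 of cells grown with 2% DMSO for 5 days. Per the series' design text, the deposited lists of each group were made from both replicates together. Each group therefore has 1 pooled value per contact, without a replicate spread, and no p-value was computed. The submitters' processing notes name the mm9 build and Bowtie. The Bowtie version, the linker handling, the tag filters, the interaction caller and its thresholds are not given in the sources used here.

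The deposited files of each group were a list of intrachromosomal connections, a list of interchromosomal connections and an edge list. The edge lists held the same 31986 uninduced and 36046 induced pairs as the intrachromosomal lists. Each connection links 2 numbered elements, and carries a deposited signal and a last column that was 0 in every line and was not used. The prefix of the element names reads as MEL, DHS (DNase hypersensitive sites), cohesin, pol2 and 1 kb. It appears to name a preset list of sites, and how that list was made is not given in the sources used here. The files hold no header and do not pair element numbers with coordinates or gene names. The number of columns of other series was 0.

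The unit of the deposited signal was inferred from its values. All 29699 pairs listed in both groups had signals whose ratio was a ratio of whole numbers with a denominator under 200 (relative tolerance 1.2e-05). After each ratio was multiplied by a random factor, 40.3% still passed. The signal was a whole number of paired-end tags (PETs) divided by the summed length of the 2 elements in kb, with the same length in both groups and no scaling to depth. Among 4594 pairs whose ratio fixed the length closely, 97.3% implied a summed length within 0.05 bp of a whole number, against 10.0% by chance. Whole PETs and element lengths were then solved jointly, with at least 2 PETs per listed pair and a summed length of at least 2000 bp imposed. A length was recovered for 24877 elements. Lengths fixed the PETs of 91.6% of 38389 pairs, the smallest whole-number solution was taken for 6.05%, and 2.33% had conflicting lengths. In simulated lists built on the same pairs, 96.4% of 38389 pairs were recovered exactly. The PETs given here are therefore values recovered from the deposited signal. Of 8634 pairs listed in 1 group only, 94.8% had at least 4 PETs. Pairs listed in both groups could have as few as 2 PETs in each, so the lists of the groups appear not to be independent of each other. The rule that admitted a pair to a list is not given in the sources used here. A pair not listed in a group was given 0 PETs there, although 1 PET is possible.

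Distance was measured as the gap between element numbers. The median gap was 25 for intrachromosomal pairs, 81541 for 100000 random pairs of linked elements and 83539 for interchromosomal pairs, from which the numbers were taken to follow the order of the genome. A gap is not a length in bp, because the spacing of elements differs along the genome.

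Folds are the PETs of an item in induced over uninduced cells, each divided by the group's total PETs over listed intrachromosomal interactions. These are relative shares, and a global gain or loss of contacts would not show in them. The 95% interval of a single item's fold is the exact Clopper-Pearson interval conditional on the summed PETs. The interval of a share is the exact Clopper-Pearson interval, which treats single PETs or interactions as independent and may be too narrow. For classes of pairs the interval comes from 1000 bootstrap draws over blocks of 100 element numbers, and covers variation between genome regions. No interval covers variation between cultures. PETs without molecular identifiers are not independent molecules, so the exact intervals cover counting error only. Chance matching of lists was taken from 100 random shifts of all element numbers. Dispersion is the mean squared Pearson residual of the induced share of PETs, which is 1 for counting error alone if no PET minimum per group cuts the pairs.

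Fold intervals were tested on simulated data. Among 4640 interactions with at least 20 PETs, 200 were given a known change. The interval lay above 1 for 10.0% of those changed 1.5-fold, for 27.5% of those changed 2-fold and for 83.5% of those changed 4-fold. It excluded 1 for 2.86% to 3.67% of the unchanged interactions. The simulated PETs held counting error only, while the dispersion of these interactions in the data was 2.59. These rates therefore need not hold for the data.

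Groups, comparisons and the first set of alternatives were fixed before the data were examined. The alternatives concerned PET minimums, depth, scaling, matching and weighting. The planned spans in bp, the share of contacts at promoters, the contacts per gene and the gene lists fixed beforehand were left out, because elements have no coordinates or names in the files and the gene table at hand is of GRCm38. Matching by overlap was replaced by identical elements. The classes of gap, partner number and element length were chosen after the data had been seen.

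The rule for named items took the 5 interactions with the most PETs in each group, the 5 shared interactions with the highest lower bound and the 5 with the lowest upper bound of the fold, the 5 unshared interactions with the most PETs in each group, and the 5 elements with the most partners. Its parts on genes could not be applied. Because the element numbers are not paired with names, only 4 element numbers are printed and the other items are described by their values. Of these 4, element 62828 is singled out because it had the lowest fold among elements with many partners, a choice made after its values were seen. The tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9.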

Results

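MEL cells are mouse red cell precursors transformed by a leukemia virus, which proliferate without maturing until an agent such as dimethyl sulfoxide (DMSO) induces them to differentiate and make hemoglobin. Cohesin is a ring-shaped protein complex that holds distant DNA segments together in loops. ChIA-PET joins and sequences the ends of DNA fragments held by a precipitated protein, and each paired-end tag (PET) reports 1 contact between 2 places. SMC1-bound contacts were listed for uninduced cells at day 0 and for cells after 5 days in 2% DMSO. Each list pooled 2 biological replicates, so every value below is 1 value per group, no difference has a replicate check, and each interval compares these pooled libraries and not the conditions. The uninduced list held 169353 PETs over intrachromosomal interactions and the induced list 260894, a ratio of 1.54. The linked places are numbered elements, for which the recovery of PETs imposed a length of at least 1 kb. Their name prefix appears to name a preset list of MEL sites (DHS, cohesin and pol2), so gaps and partners refer to those elements only. Of the elements, 28163 carried an intrachromosomal interaction in either group.

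The first comparison asked how many cohesin-bound interactions were seen before and after induction. The uninduced list held 31986 intrachromosomal interactions and the induced list 36046, a ratio of 1.13. Interactions carried more PETs in the induced list, with a median of 5 PETs against 4. At least 10 PETs were found for 7047 induced and 3624 uninduced interactions, and at least 50 PETs for 276 and 68. The deposited signal had a median of 1.05 PETs per kb in induced and 0.816 PETs per kb in uninduced cells. The 5 strongest uninduced interactions had 105 to 200 PETs, and the 5 strongest induced interactions had 191 to 255 PETs. Only 1 interaction was among the 5 strongest of both groups. The difference in number depended on the difference in PETs. After the induced PETs were thinned at random to the uninduced total, 29090 induced interactions kept at least 2 PETs, a ratio of 0.909 to the uninduced list, and with at least 4 PETs the ratio was 0.953. Thinning only the induced list gives ratios under 1 by itself. In 100 simulations without a change, the PETs of each pair were split by the group totals and listed by the inferred rule. The mean ratio was 1.14 before thinning (lowest 1.136, observed 1.127). It was 0.965 after thinning with at least 2 PETs (lowest 0.954) and 0.981 with at least 4 (lowest 0.964). Each observed ratio lay under the lowest simulated one. The simulations held counting error only and applied the inferred rule to pairs already selected by it, so no change in number can be read from this.

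The second comparison asked how far the contact map of differentiated cells was already present in uninduced cells. Most interactions were common to both lists. The 29699 shared interactions made up 92.8% of the uninduced list (exact 95% interval 92.6 to 93.1%) and 82.4% of the induced list (82.0 to 82.8%). After random shifts of one list along the genome, a mean of 0.181% and at most 0.231% of the uninduced interactions were matched. The 2287 interactions listed only in uninduced cells held 6.85% of that group's PETs, and 53 of them had at least 10 PETs. The 6347 listed only in induced cells held 14.4% of the PETs there, and 557 of them had at least 10 PETs. The induced list held 1.54 times the uninduced PETs, so interactions reach a PET minimum more readily there. Shared and unshared interactions were not compared at equal PETs, so these numbers do not show a gain of contacts on induction. The 5 strongest uninduced-only interactions had 13 to 17 PETs and joined elements 49 to 176 positions apart. The 5 strongest induced-only interactions had 28 to 35 PETs and joined elements 8 to 28 positions apart. The lists appear to have been made jointly, since almost all pairs listed in 1 group only had at least 4 PETs, while 51.6% of the shared pairs had only 2 or 3 PETs in uninduced and 40.6% in induced cells. Such a rule raises the shared percentages, which the random shifts do not cover, and of the interactions with at least 4 PETs in their own group 87.0% of the uninduced and 74.5% of the induced were shared.

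The third comparison concerned the gap in element numbers spanned by the contacts, which is not a length in bp. Contacts over intermediate gaps took a larger share of the PETs in induced cells, and contacts over long gaps a smaller share. Pairs 6 to 25 elements apart held 35.1% of the uninduced PETs (exact 95% interval 34.9 to 35.4%) and 42.3% of the induced PETs (42.2 to 42.5%). Pairs over 50 elements apart held 30.3% of the uninduced (30.1 to 30.5%) and 24.0% of the induced PETs (23.9 to 24.2%). The median gap was 26 elements in uninduced and 24 in induced cells, with quartiles of 11 and 56 against 10 and 52. Weighted by PETs it was 29 and 24, and among interactions with at least 10 PETs it was 34 and 25. Interactions listed only in uninduced cells had a median gap of 42 elements, and those listed only in induced cells had a median gap of 21.

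The fold in PET share, induced over uninduced, was highest at intermediate gaps over all pairs. It was 0.954 for pairs 1 to 5 elements apart (95% bootstrap interval 0.928 to 0.980), 1.20 for 6 to 25 (1.19 to 1.22) and 0.980 for 26 to 50 (0.959 to 1.00). It was 0.808 for pairs 51 to 100 apart (0.787 to 0.832) and 0.762 for pairs over 100 apart (0.731 to 0.794). In finer classes the highest fold was 1.25, at gaps of 11 to 12 elements (1.20 to 1.31), and the lowest was 0.750, at 101 to 150 elements (0.714 to 0.787). The fold of pairs over 50 apart divided by that of pairs 6 to 25 apart was 0.658 (0.637 to 0.679), a value that no scaling can change. Single folds do depend on it. Without scaling, PETs were higher in induced cells in both classes, at 1.22 times the uninduced number for pairs over 50 apart and 1.86 times for pairs 6 to 25 apart, and with scaling by the median ratio of shared interactions these values were 1.05 and 1.59. Among shared pairs with at least 20 PETs, on the same scale to total listed PETs, the fold of pairs 1 to 5 apart was 1.08 (1.02 to 1.14), against 1.05 (1.04 to 1.07) for all such pairs, so that the lower share at short range was not found there. It also depended on element length. At 1 to 5 elements apart the fold was 1.51 for pairs of 2000 bp in sum and 1.19 for pairs over 2000 and up to 4000 bp, against 0.940, 0.889 and 0.888 in the longer classes. For pairs of 2000 bp the fold had no peak and went from 1.51 and 1.46 at the shortest classes of distance to 1.22, 0.992 and 0.906 at the longer ones.

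**Figure D1:**
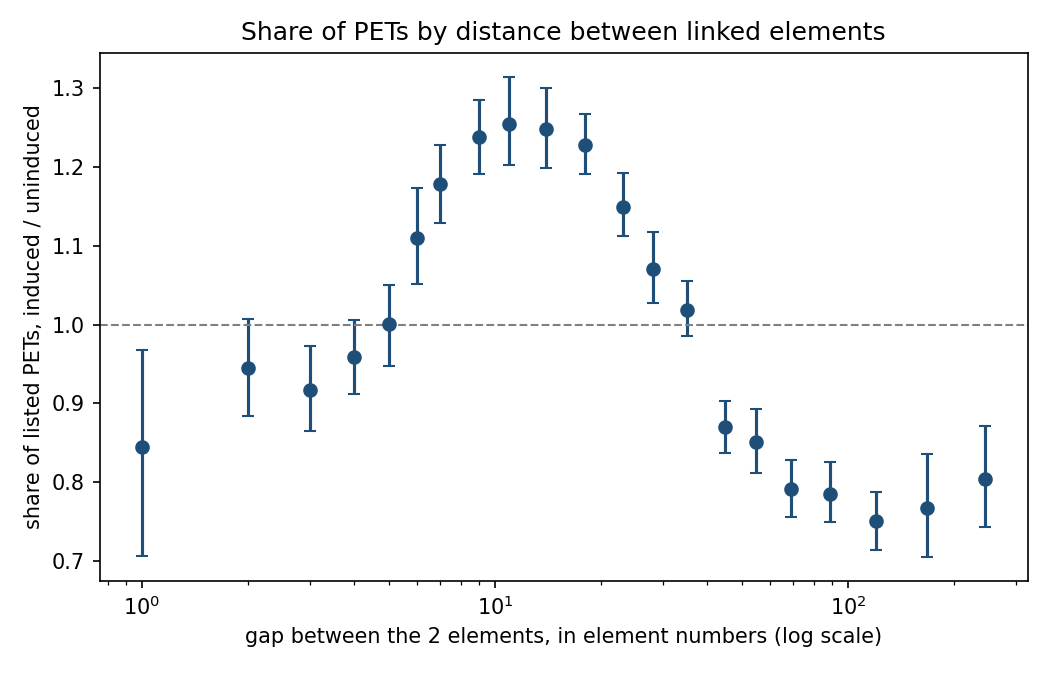
Share of listed intrachromosomal PETs in induced over uninduced cells (y axis, ratio without unit) against the median gap between the linked elements in each of 21 classes (x axis, element numbers, log scale). Points are folds, bars are 95% block bootstrap intervals, and the dashed line marks 1. The fold is highest, 1.25, at gaps of 11 to 12 elements and lies between 0.750 and 0.851 in every class over 50 elements.

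The fourth comparison asked which of the shared interactions differed in strength. Over all 29699 shared interactions, the fold interval lay above 1 for 616 and below 1 for 937, together 5.23%. Their median fold was 0.757, the tenth percentile was 0.325 and the ninetieth was 1.95, and the dispersion of their induced share was 1.18. These values are shaped by the PET minimum of a listed pair. Of the shared interactions, 4922 had exactly 2 PETs in each group, equal counts that the scaling to total PETs puts below 1. The minimum of 2 PETs in each group also narrows the induced share, so 1.18 cannot be set against 1. The balance of the calls depended on the scaling and on how many PETs were required. Higher folds were 39.7% of these calls with scaling to total PETs, 56.0% with scaling to the PETs of shared interactions (842 above and 661 below), 81.3% with the median ratio (1566 and 360) and 92.4% without scaling (2290 and 188). With at least 20 PETs over both groups, 4640 interactions remained, of which 505 lay above 1 and 351 below, 59.0% of the calls being higher. Their median fold was 1.07, the tenth percentile was 0.502 and the ninetieth was 2.41. The dispersion of their induced share was 2.59, and 3.72 for the 795 interactions with at least 50 PETs.

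The distance also separated these calls. With at least 20 PETs, the interactions above 1 had a median gap of 17 elements and those below 1 a median gap of 56, against 28 for all 4640. Pairs over 50 elements apart made up 11.1% of those above and 54.7% of those below. The largest lower bound belonged to the contact between elements 264076 and 264117, which lie 41 positions apart. It had 5 PETs in uninduced and 79 in induced cells, or 0.685 and 10.8 PETs per kb, a fold of 10.3 (exact 95% interval 4.21 to 32.5). The folds of the 5 interactions with the highest lower bounds ran from 8.44 to 12.7, and those of the 5 with the lowest upper bounds from 0.0649 to 0.108. The first of the latter joined elements 68 positions apart and had 20 PETs in uninduced and 2 in induced cells, a fold of 0.0649 (0.00736 to 0.267).

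The fifth comparison concerned the elements themselves and their number of partners. In uninduced cells 24992 elements were linked and in induced cells 27370, with 24199 in both, 793 in uninduced cells only and 3171 in induced cells only. Linked elements had a mean of 2.56 partners in uninduced and 2.63 in induced cells. At least 20 partners were seen for 49 and 53 elements. Partner numbers had a Spearman correlation of 0.853 between the groups across elements, which are not independent replicates. It was 0.461 when only interactions with at least 5 PETs were counted. The 5 elements with the most partners were the same in both groups. The first, element 129984, had 72 partners in uninduced and 65 in induced cells. Its 773 uninduced and 893 induced PETs gave a fold of 0.750 (exact 95% interval 0.680 to 0.827), although its PETs were higher in induced cells without scaling.

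Elements with many partners took a smaller share of the PETs in induced cells. Of the 48 elements with a mean of at least 20 partners, 26 had a fold interval below 1 and 1 above, and the median fold was 0.788. The exact intervals cover counting error only. These 48 elements are also not independent, since some lie close together and an interaction between them counts for each. Their partner numbers went both ways, with 20 having more partners in uninduced and 18 more in induced cells. With the median-ratio scaling, 8 of the 48 lay below 1 and 10 above, and without scaling 3 lay below and 25 above. Relative to all interactions, the fold by partner number went from 1.25 (1.20 to 1.30) for pairs whose better-connected element had over 1 to 2 partners to 0.812 (0.777 to 0.852) for those with over 16. Among shared pairs with at least 20 PETs the same classes had folds of 1.15 (1.07 to 1.25) and 0.911 (0.863 to 0.971), scaled alike. At short distance the fold did not fall with partner number in the classes up to 16 partners and was lowest above. No intervals were computed for these values. At 1 to 5 elements apart the fold was 0.929, 0.960, 0.966, 0.972 and 0.967 in the classes up to 16 partners and 0.822 above. Pairs with over 16 partners had a fold of 1.00 at 6 to 25 elements apart and 0.601 at over 100. The class with a mean of up to 1 partner over the groups had a fold of 1.38 (1.26 to 1.51) over all pairs. Of its 994 pairs, 373 were listed in induced cells only and 76 in uninduced cells only. Listing in 1 group lowers the mean partner number, so it enters this class by itself. Only 13 of its pairs were shared with at least 20 PETs, with a fold of 0.809 (0.537 to 1.24). Pairs of elements of 1 kb each, 2000 bp in sum, had a fold of 1.23 (1.18 to 1.27), and pairs of over 9000 bp a fold of 0.872 (0.839 to 0.905). Among shared pairs with at least 20 PETs these were 1.17 (1.10 to 1.23) and 0.969 (0.919 to 1.02), against 1.05 (1.04 to 1.07) for all such pairs.

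**Figure D2:**
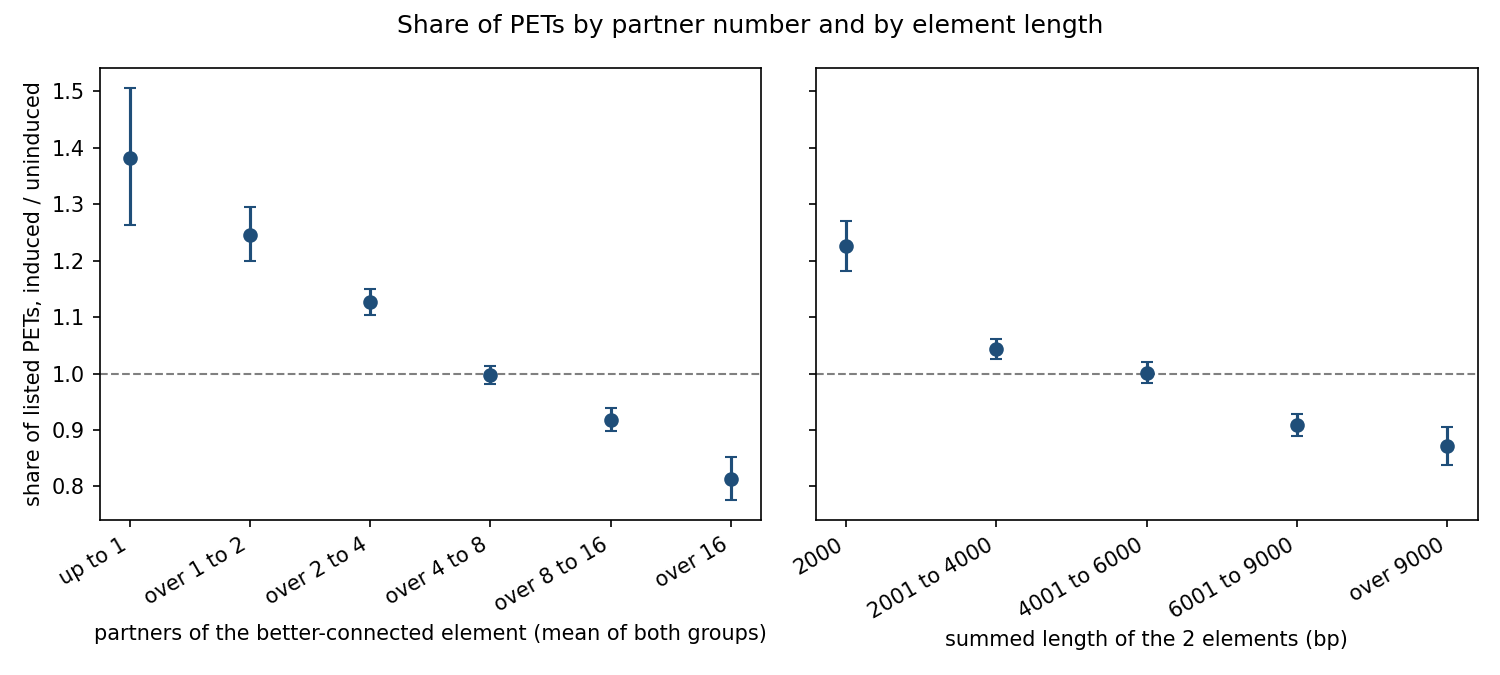
Share of listed intrachromosomal PETs in induced over uninduced cells (y axis, ratio without unit) by the mean partner number of the better-connected element of a pair (left) and by the summed length of both elements in bp (right). Points are folds over all listed pairs, bars are 95% block bootstrap intervals, and the dashed line marks 1. The fold goes from 1.38 (0.809 over the 13 shared pairs of this class with at least 20 PETs) to 0.812 with partner number and from 1.23 to 0.872 with length.

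Among the elements with at least 20 partners, element 62828 had the lowest fold. It spans 21301 bp, the longest recovered element, and had 60 partners in uninduced and 53 in induced cells. Its PETs were 384 in uninduced and 224 in induced cells, lower even without scaling, with a fold of 0.379 (0.320 to 0.448). Of 50 partners seen in both groups, 48 had a fold below 1. Without scaling, 29 of them had fewer PETs in induced cells, 15 had equal PETs, 13 of these at 2 PETs in each group, and 6 had more. A further 10 partners were listed in uninduced cells only and 3 in induced cells only. Pairs 1 to 5 elements apart within 100 positions of it, but without the element itself, had a fold of 0.337 (0.225 to 0.497), from 79 uninduced and 41 induced PETs. The other 69 pairs there had a fold of 0.582 (0.494 to 0.687), from 311 and 279 PETs. Of 4862 elements with at least 50 PETs, 618 had an interval above 1 and 704 below.

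**Figure D3:**
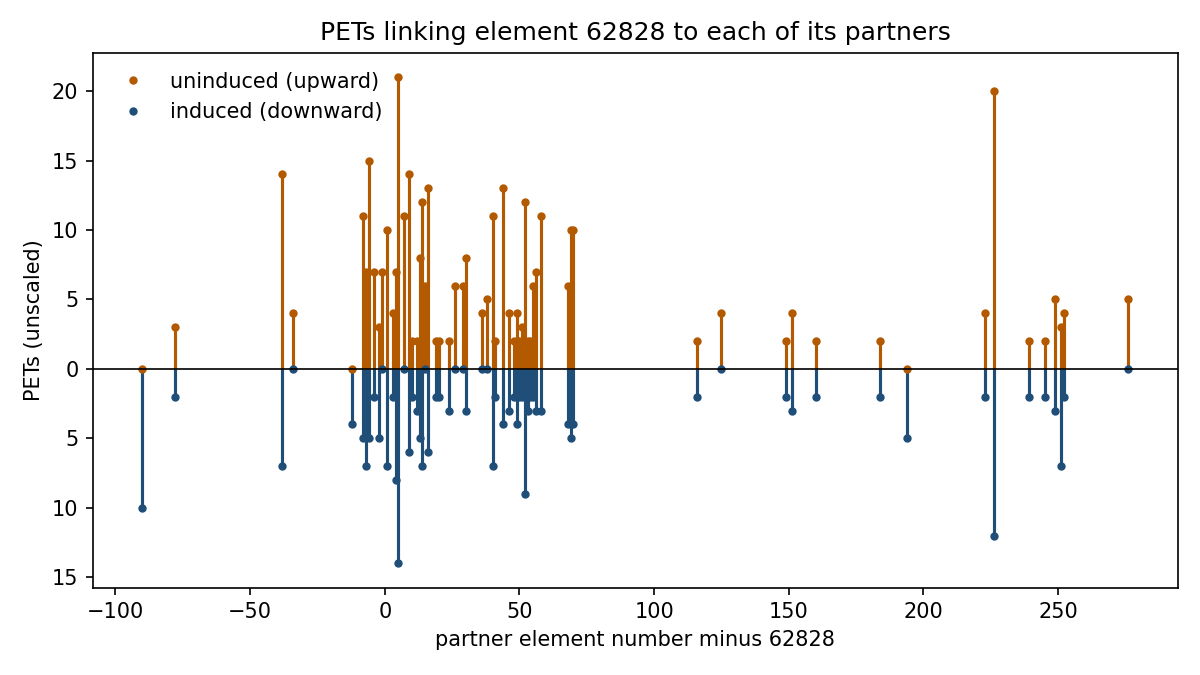
PETs (y axis, unscaled counts) between element 62828 and each of its partners in uninduced cells (upward) and induced cells (downward), against the partner's element number minus 62828 (x axis). Each line is 1 partner, and a point at 0 marks a partner not listed in that group. The upward lines sum to 384 PETs and the downward lines to 224.

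The last comparison concerned contacts between chromosomes. These were few and largely common to both lists. The uninduced list held 52 and the induced list 53, with 49 in both. They carried 241 PETs in uninduced and 230 in induced cells, or 0.142% and 0.0881% of all listed PETs. Relative to the intrachromosomal PETs, the fold was 0.619 (exact 95% interval 0.515 to 0.745), while the unscaled sums differed little. The strongest had 39 PETs in uninduced and 40 in induced cells. The fold interval of 1 connection lay below 1, and that of 0 connections above, while the median was 3 PETs in uninduced and 2 in induced cells. Of the 56 connections in either list, 13 joined elements that both also carried an intrachromosomal interaction.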

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

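No paired analysis was possible because the deposited lists pool both replicates of each group, so that no replicate number can be followed, and leaving out a replicate could not be done either. Matching within 1 element number, merging of neighbouring elements, the 4-PET minimum and all settings of the long-over-middle fold were chosen after seeing the data. Of 38 alternatives, 13 left their value within its 95% interval or, for a count, within 1.5 times, 20 moved it and 5 reversed it, and the causes were not tested. Among the 13, matching by identical elements, in either list, and the use of the edge lists repeated the main value by construction. They are no check of it. The ratio of interaction numbers, 1.13, was 1.43, 1.55 and 1.94 with at least 4, 5 and 10 PETs, and it reversed to 0.909 after thinning to equal listed PETs, where simulations without a change, added after seeing the data, gave 0.954 to 0.971. Sequencing depth itself is not given in the sources used here. The median gap, induced minus uninduced, was -2 elements, -5 when weighted by PETs and -9 with at least 10 PETs. The shared percentage of uninduced interactions was 87.0% with at least 4 PETs, 98.5% with at least 10 PETs and 94.4% when matched within 1 element number. For induced interactions these were 74.5%, 92.1% and 86.6%. Each PET minimum was applied to the named group only, while the other group needed only to list the pair. The 616 folds above and 937 below 1 became 1566 and 360 with the median ratio, and 2290 and 188 without scaling. With at least 20 PETs, where fewer interactions were counted, 351 lay below. The balance reversed each time, from 39.7% of the calls above 1 to 81.3% with the median ratio, 92.4% without scaling, 56.0% with the PETs of shared interactions and 59.0% with at least 20 PETs. The correlation of partner numbers, 0.853, was 0.461 with at least 5 PETs and 0.867 with neighbouring elements merged. The long-over-middle fold, 0.658, stayed under 1 in all 8 settings tried, and was 0.734 over shared pairs and 0.681 with 1 PET for each unlisted pair. Among the 8, thinning of the induced PETs, at 0.657, keeps this ratio on average by construction and is no check of it. The alternatives that need coordinates, gene names or a threshold (spans of at least 20 kb, 5 kb and half-anchor overlap, 5 kb merging, stricter significance, and every alternative for promoters, gene lists and anchor classes) were not run, since the elements are known by number only and the last column is 0 throughout. Depth limits single interactions, for which the median is 4 PETs in uninduced and 5 in induced cells.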

Other observations

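Folds in PET share also varied between stretches of the genome. Of 686 windows of 100 element numbers with at least 200 PETs, 100 had a fold interval above 1 and 144 below, with an SD of 0.361 for the log2 fold over windows. The intervals cover counting error only, and the balance of these calls depends on the scaling to total PETs. The SD was not set against that of counting error or of the class trends. The 3 windows with the highest folds had 2.69 (exact 95% interval 1.95 to 3.79), 2.52 (1.91 to 3.35) and 2.20 (1.64 to 3.01). The 3 with the lowest had 0.399 (0.298 to 0.532), 0.414 (0.350 to 0.488) and 0.424 (0.375 to 0.479), and the last of these contains element 62828. Interactions that share an element varied together weakly. Over 4963 pairs of interactions with at least 20 PETs that share an element, the deviations from the fold of their distance, partner and length class had a correlation of 0.0986, against -0.0362 to 0.0323 in 100 shuffles. The dispersion of the induced share, 2.59, was 2.22 after those classes were taken into account.

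Linked elements formed 2686 connected groups in uninduced and 2688 in induced cells. The largest held 293 and 401 elements. Closed triangles numbered 9607 and 11306, and the closed share of paths over 3 elements was 21.8% and 22.5%. The induced list held more interactions and PETs, and these network values were not compared at equal PETs.

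All tests of explanations below, except that of random ligation among pairs with at least 50 PETs and that of differences between cultures, were chosen after the result they measure had been seen.

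Pairs over 50 elements apart had a lower fold than pairs 6 to 25 apart, at a ratio of 0.658. The number of listed PETs and the listing rule cannot be the whole cause, since the ratio was 0.658 (0.629 to 0.690) among 1242 long and 1805 middle pairs that were listed in both groups with at least 20 PETs. A few elements with many partners cannot be either, since it was 0.666 (0.645 to 0.687) without the 100 elements that had over 16 partners. Random ligation spreads over many pairs with few PETs each, yet the ratio was 0.664 (0.610 to 0.723) among pairs with at least 50 PETs. A shift of cohesin contacts towards intermediate gaps in element number on induction is a hypothesis. It cannot be told apart from other differences between the cultures or libraries, such as fragment length or ligation, with 1 pooled value per group. Gaps are not lengths in bp, and the spacing of elements could not be taken into account.

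Element 62828 was picked as the lowest of 48 elements with many partners, which alone favours a low value. Its fold divided by the 0.780 expected from pairs of the same distance, partner and length classes was 0.486, while the other 47 elements ran from 0.525 to 1.58 on this measure. It thus lay under the lowest of them by less than their SD of 0.282 (log2), and the class trends together with the choice of the lowest stay open. Its neighbourhood was lower too, with a fold of 0.533 (0.391 to 0.703, resampled pairs) over 88 pairs within 100 positions without the element, so a lower level of the whole stretch may account for part of the pattern. An equal loss over the stretch as the whole cause was not settled: the fold of the element over that of its neighbours was 0.711 (0.505 to 0.996), at 0.650 (0.469 to 0.964) against the longer pairs and 1.12 (0.685 to 2.01) against the short ones.

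Connections between chromosomes lay close to one another. Of 56 connections, 15 had another within 1000 element numbers at both ends, against a mean of 1.95 and at most 8 in 100 random re-pairings of the same ends, so chance pairing does not account for them. Candidate explanations are chromosome rearrangements carried by the MEL line, which would place formerly distant elements side by side in both groups, and reads that map equally well to near-identical sequences. For the latter, 10 of the 15 had their neighbour within 10 element numbers, as single duplicated sequences would give, while 5 had it 11 to 1000 away. These numbers do not decide between the explanations, which would need the positions and sequences of the elements.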
